A study of Homo sapiens with 4 samples.

How the data were processed

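RNA was sequenced from RPMI 8226, a human multiple myeloma cell line, after transfection with a locked nucleic acid antisense oligonucleotide (LNA ASO, a short synthetic oligonucleotide with modified sugars that pairs with a chosen RNA). The ASO against CELF2 was used at 5 nM and compared with a control LNA ASO after 72 hours, with 2 libraries per group, per the labels. The labels give no dose for the control. The number in each library's label may mark a replicate or an oligonucleotide, and no sequence of either ASO was used here. No label says that the libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

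The labels describe the library preparation in conflicting ways. The design text names poly(A) selection, while the sample protocol names removal of ribosomal RNA by RNase H followed by random-hexamer priming. RNAs without a poly(A) tail are kept by one method and largely lost by the other. Such RNAs were abundant in all 4 libraries. The 7SL gene RN7SL1 took 2.54% to 4.77% of counts, and the small nucleolar RNA gene SNORD3A had 3679.32 to 6064.38 CPM. These values argue against poly(A) selection, but no label settles the method, so the level of such RNAs relative to mRNA has no fixed meaning here. Paired reads of 150 bases were made on a NovaSeq X Plus per the labels.

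The deposited values were whole-number read counts per gene with no normalization by the authors that the values show. Per the submitters' processing notes, bcl2fastq, STAR 2.7.11b, Subread, featureCounts 2.0.8, Salmon 1.10.0 and the GRCh38 build were used. The annotation release, the strand setting and the treatment of reads that map to several genes are not given in the sources used here. Without a stated strand setting, reads of a gene and of an antisense partner cannot be told apart. The table held 79029 rows, of which 78932 were Ensembl genes. The other 97 rows were spike-in or reporter sequences holding 1 to 3 counts per library, and they were left out. Symbols were found for 61481 gene IDs in a name table. Positions and gene types came from GENCODE 29 on GRCh38, which held 57356 of the IDs. MALAT1 had 9 and 5 counts in the control libraries and 19 and 10 in the CELF2 ASO libraries, and RN7SK, RMRP and RPPH1 were listed at 0 in all 4, so genes that overlap other annotated genes or have near-identical copies are uncertain in this table. This holds for histone genes, HSPA1A and HSPA1B, the keratins KRT6C, KRT81 and KRT86, PRSS1, and immunoglobulin segments.

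Total counts were 29161298 and 24493148 in the control libraries and 26061900 and 23599190 in the CELF2 ASO libraries. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 19511. Libraries were scaled by TMM, and the groups were compared by the two-sided quasi-likelihood test with robust estimation and no covariate. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors of log2 fold changes were taken as the absolute fold change over the square root of the F statistic. CPM values are read counts scaled by the TMM-adjusted library size. Replicates were compared by a chi-square test of their counts. The statistic per degree of freedom was 3.85 for the control pair over 18303 genes and 22.5 for the CELF2 ASO pair over 19464 genes, so the libraries of each pair differed beyond sampling noise.

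A set of 26 gene lists was fixed before the data were examined and tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with adjustment over the lists. The test was repeated with an estimated correlation. That version takes its degrees of freedom from the libraries, so with 2 per group it can hardly call any list. A further repeat used fry, which asks whether a list's genes move one way on balance and does not compare them with other genes. The genes named in the text were set by a rule fixed at the same time. It took CELF2, the 8 largest rises and 8 largest falls among genes past the threshold with a mean log2 CPM of at least 1, a symbol and groups that did not overlap, up to 2 members of each list with the smallest adjusted p, and the 3 smallest p-values in each direction. Members of a list could be named with their values. CELF1, MX1, ISG15, IFIT2, DDIT3, ATF4, ATF5, HSPD1, HSPE1, XBP1, HMOX1, IGLC2, IGLV2-14, MYC, SDC1, TNFRSF17 and CD38 were named after their values were seen.

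The analysis was tested on simulated counts with 200 changed genes. The counts were drawn from the means of these libraries and from a spread that both groups shared. Over 18810 simulated genes, 33 of 67 changes of 1.5-fold, 58 of 67 of 2-fold and 66 of 66 of 4-fold were recovered, with 4 false calls. A correction for GC content and transcript length was tested on a simulated GC trend with a depth gap between the groups. Over 17699 genes, false calls went from 3415 without the correction to 6 with it, and 108 of 122 changes of 2-fold or 4-fold were still found.

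Alternatives fixed before the data were examined were RLE scaling, library totals alone, no filter on low counts, a filter of 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, the older quasi-likelihood method, the label's number as a block, and leaving out each library. Voom with a weight per group, the control libraries summed to 1, and the GC and length correction were added after seeing the data.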

Results

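Gene expression was measured by RNA sequencing in RPMI 8226 myeloma cells carrying a control LNA ASO or an LNA ASO against CELF2, an RNA-binding protein that regulates splicing and mRNA stability. Each group had 2 libraries, with total counts between 23599190 and 29161298. The 4 libraries make 1 comparison, which asks which transcripts differ between cells given the CELF2 ASO and cells given the control ASO at 72 hours.

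CELF2 itself (ENSG00000048740, GRCh38 chromosome 10, 10798397 to 11336675, plus strand) was 2.43-fold lower with the CELF2 ASO. Its level was 128 ± 0.0805 CPM in the control libraries and 52.7 ± 5.53 CPM in the CELF2 ASO libraries (SD, n = 2 each). The log2 fold change was -1.28 with a standard error of 0.09 (edgeR adjusted p = 3.74e-05). The antisense gene CELF2-AS1, which lies within the CELF2 locus on the minus strand, had a log2 fold change of -0.78 (edgeR adjusted p = 0.0304), and its reads cannot be separated from those of CELF2 without a stated strand setting. The paralog CELF1 had a log2 fold change of 0.20 with a standard error of 0.10 and did not pass (edgeR adjusted p = 0.117), although it passed with library totals alone (adjusted p = 0.0198) and without CELF2_LNA_ASO replicate 1 (adjusted p = 3.97e-08), where the spread comes from the control pair alone. In the list of CELF and MBNL splicing factors, 2 of 5 tested members rose and 2 fell, and the list was not shifted, with a median of 0.20 against a mean of -0.01 (camera adjusted p = 0.951, direction down), and 4 changed when adjusted over the list alone. MBNL2 rose 2.32-fold.

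Expression changed broadly. Of 19511 genes tested, 10848 passed the threshold, 5388 higher and 5460 lower with the CELF2 ASO, and 5010 of them changed at least 2-fold. The calls made up 55.6% of the tested genes, and 8075 of 12754 protein-coding genes were called. A number of changed list members near these shares therefore says little about that list. With libraries scaled by totals alone, 6333 genes were higher and 4539 lower. The 2 groups did not overlap for 15530 of the 19511 tested genes (79.6%), where chance gives no overlap in 33.3%. The CELF2 ASO libraries differed more from each other than the control libraries did, with a biological coefficient of variation of 13.7% against 3.58%. Without control_LNA_ASO replicate 1 the higher genes numbered 3564. A fit without a control library takes its spread from the CELF2 ASO pair alone, and a fit without a CELF2 ASO library takes it from the control pair alone.

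**Figure D1:**
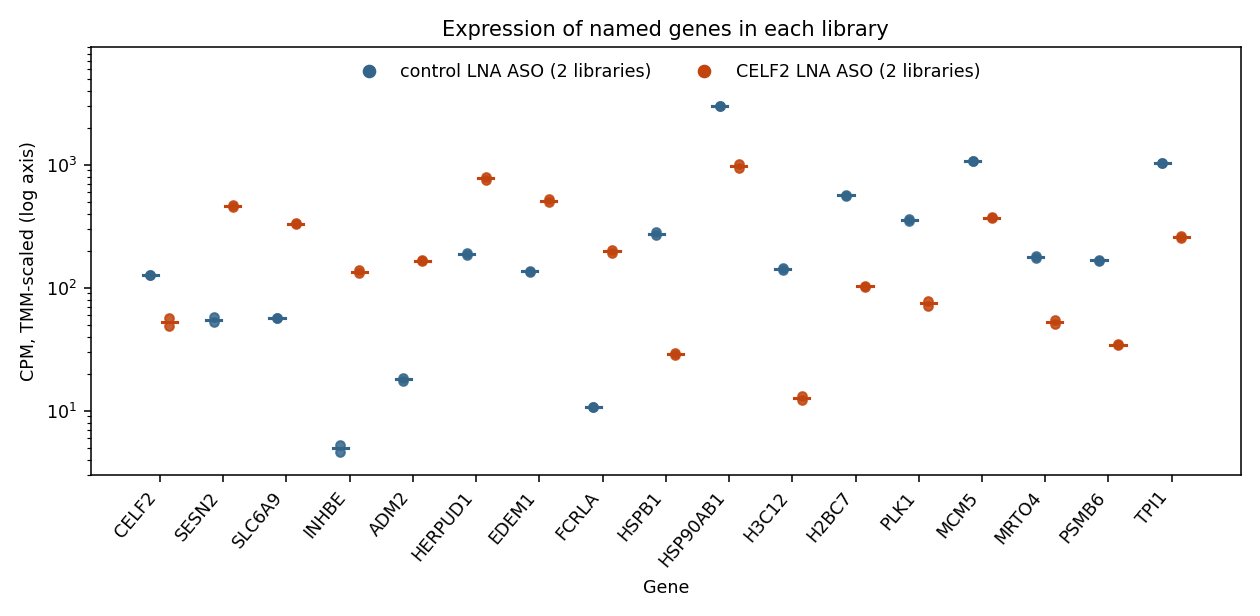
CPM of 17 named genes (x axis) on a log y axis, with a point for each library and a bar at each group mean, control LNA ASO in blue and CELF2 LNA ASO in orange. CELF2 lies at 128 CPM in the control and 52.7 CPM in the CELF2 ASO libraries. The points of the groups are separate for every gene shown, as they are for all 10848 called genes.

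Stress-response genes driven by the transcription factor ATF4 rose together. Of 33 tested members of the integrated stress response list, 31 rose and 1 fell, with a median log2 fold change of 2.30 (camera adjusted p = 2.06e-37, or adjusted p = 0.24 with an estimated correlation). Adjusted over the list alone, 32 changed. SESN2, an inhibitor of mTORC1 signalling, rose 8.44-fold, from 54.8 ± 3.44 to 463 ± 10.1 CPM (SD, n = 2), and the glycine transporter SLC6A9 rose 5.85-fold. DDIT3, which encodes the transcription factor CHOP, rose 25.5-fold, and ATF4 itself rose 4.79-fold. ATF5 fell 3.04-fold. INHBE, an inhibin beta subunit, rose 27.4-fold and the peptide hormone gene ADM2 rose 9.26-fold, both among the 3 rises with the smallest p.

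Genes of the unfolded protein response of the endoplasmic reticulum also rose. In that list 20 of 25 members rose and 1 fell, with a median of 0.79 (camera adjusted p = 4.02e-09, or adjusted p = 0.242 with an estimated correlation), and 21 changed when adjusted over the list alone. HERPUD1 rose 4.12-fold and EDEM1 3.75-fold, both parts of the degradation of misfolded proteins. XBP1, a regulator of this response, had a log2 fold change of 0.02 with a standard error of 0.07 (edgeR adjusted p = 0.82), and its sign depended on the setting. The counts measure total XBP1 mRNA and not its activity.

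Heat shock genes fell. Of 15 members of the heat shock list, 13 fell and none rose, with a median of -1.63 (camera adjusted p = 4.54e-14, or adjusted p = 0.248 with an estimated correlation), and 13 changed when adjusted over the list alone. HSPB1, a small heat shock protein, fell 9.5-fold, from 276 ± 9.21 to 29 ± 0.566 CPM (SD, n = 2), and HSP90AB1 fell 3.09-fold. Of the mitochondrial chaperonin genes, HSPE1, which overlaps a readthrough gene, fell 2.38-fold (edgeR adjusted p = 8.33e-05). HSPD1 had a log2 fold change of 0.09 (edgeR adjusted p = 0.344) and passed with library totals alone (adjusted p = 0.0364) and, with the spread of the control pair alone, without CELF2_LNA_ASO replicate 1 (adjusted p = 0.00316). Proteasome subunit genes fell as well, 27 of 31 with 1 rise and a median of -0.76 (camera adjusted p = 8.14e-10, or adjusted p = 0.265 with an estimated correlation; 29 changed when adjusted over the list alone). PSMB6, a catalytic subunit, fell 4.85-fold and PSMB3 fell 2.71-fold.

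Proliferation genes were lower. In the DNA replication and G1/S list, 34 of 41 fell and 1 rose, with a median of -0.60 (camera adjusted p = 6.46e-10, or adjusted p = 0.24 with an estimated correlation). In the G2 and mitosis list, 33 of 38 fell and 1 rose, with a median of -0.70 (camera adjusted p = 5.38e-13, or adjusted p = 0.325 with an estimated correlation). The counts adjusted over the list alone were 35 and 34. The replicative helicase gene MCM5 fell 2.88-fold, the thymidine kinase gene TK1 2.48-fold, the mitotic kinase gene PLK1 4.75-fold and CDC20 4.05-fold. Replication-dependent histone genes fell in 42 of 47 cases with none rising, with a median of -1.61 (camera adjusted p = 8.52e-36, or adjusted p = 0.24 with an estimated correlation, with 42 changed when adjusted over the list alone). H3C12 fell 11.2-fold and H2BC7 fell 5.51-fold. These genes made up 1.69% and 1.61% of counts in the control libraries and 0.57% and 0.577% in the CELF2 ASO libraries. Their mRNAs lack a poly(A) tail and are near-identical copies, so single members are uncertain.

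Growth and metabolic lists fell too. Of 40 MYC target and ribosome biogenesis genes, 35 fell and none rose, with a median of -1.02 (camera adjusted p = 1.78e-16, or adjusted p = 0.24 with an estimated correlation, with 36 changed when adjusted over the list alone), and MRTO4 fell 3.38-fold and RRP9 3.34-fold. MYC had a log2 fold change of -0.56 (edgeR adjusted p = 0.0334), a call lost with library totals alone (adjusted p = 0.106), no filter (0.108), the GC and length correction (0.0607) and without control_LNA_ASO replicate 1 (0.0622). Of 48 nuclear-encoded oxidative phosphorylation genes, 40 fell and 3 rose, with a median of -0.57 (camera adjusted p = 1.7e-08, or adjusted p = 0.248 with an estimated correlation, with 44 changed when adjusted over the list alone), and ATP5MC1 fell 3.86-fold and NDUFB10 3.09-fold. Of 33 glycolysis and hypoxia genes, 24 fell and 3 rose, with a median of -0.84 (camera adjusted p = 1.7e-08, or adjusted p = 0.24 with an estimated correlation, with 29 changed when adjusted over the list alone), and the glycolytic enzyme gene TPI1 fell 4.01-fold and the glucose transporter gene SLC2A1 3.01-fold. Of 24 cholesterol synthesis genes, 16 fell and 4 rose, with a median of -0.51 (camera adjusted p = 0.000609, or adjusted p = 0.248 with an estimated correlation, with 20 changed when adjusted over the list alone), and ACAT2 fell 3.19-fold and EBP 2.16-fold. Of 34 splicing regulators, 27 fell and 2 rose, with a median of -0.55 (camera adjusted p = 4.27e-06, or adjusted p = 0.242 with an estimated correlation, with 29 changed when adjusted over the list alone), and SRSF2 fell 4.79-fold and U2AF2 2.35-fold.

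Cytosolic ribosomal protein genes moved slightly upward, 25 of 54 rising and 4 falling with a median of 0.26 (camera adjusted p = 0.0287, or adjusted p = 0.899 with an estimated correlation, with 29 changed when adjusted over the list alone). RPL22 rose 2.03-fold and RPL3 1.75-fold. The call on this list was lost without control_LNA_ASO replicate 1 (adjusted p = 0.097) and with the control libraries summed to 1 (adjusted p = 0.118). Mitochondrially encoded mRNAs were not shifted, 3 of 13 rising and 5 falling with a median of 0.05 (camera adjusted p = 0.951), and 8 changed when adjusted over the list alone. MT-ND6 rose 1.73-fold and MT-ND3 fell 1.64-fold. Mitochondrial ribosomal RNA took 0.075% of counts in CELF2_LNA_ASO replicate 1 and 0.00611% in CELF2_LNA_ASO replicate 2, against 0.00949% and 0.00162% in the control libraries.

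**Figure D2:**
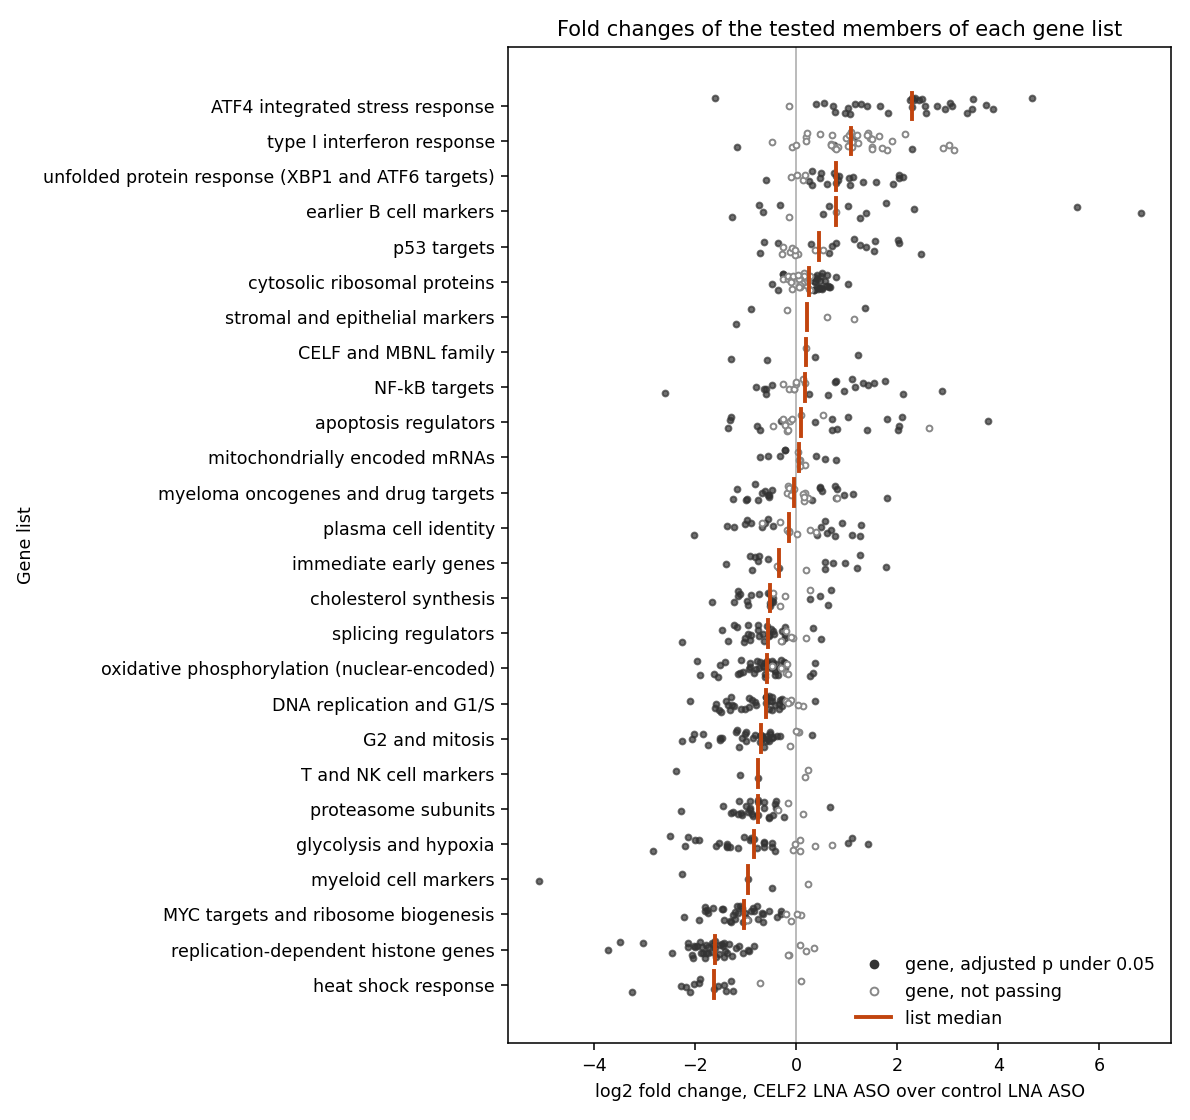
Log2 fold change of the CELF2 ASO over the control ASO (x axis) for each tested member of the 26 gene lists (y axis), filled where the adjusted p is under 0.05, with a bar at each list's median. The medians run from -1.63 for the heat shock response to 2.30 for the ATF4 integrated stress response.

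Plasma cell and B cell genes changed in both directions. Of 28 plasma cell identity genes, 10 rose and 10 fell, and the list was not shifted (median -0.13, camera adjusted p = 0.951, with 20 changed when adjusted over the list alone). GPRC5D fell 4.05-fold and CREB3L2 rose 1.88-fold. SDC1, the surface proteoglycan CD138, fell 2.34-fold, a call lost with no filter (edgeR adjusted p = 0.0569), and CD38 rose 2.43-fold. TNFRSF17, which encodes BCMA, was 2-fold lower (edgeR adjusted p = 0.0386), a call lost without control_LNA_ASO replicate 1 (adjusted p = 0.156) or replicate 2 (adjusted p = 0.149), with these libraries summed to 1 (0.155), with library totals alone (0.0592), with no filter (0.0965) and with the GC and length correction (0.0592). Of 15 markers of earlier B cells, 9 rose and 4 fell, with a median of 0.79 that stayed at 0.79 with genes of 3 or fewer counts at their bound (camera adjusted p = 0.0292, or adjusted p = 0.265 with an estimated correlation, with 13 changed when adjusted over the list alone). This call was lost without CELF2_LNA_ASO replicate 1 (adjusted p = 0.145) or replicate 2 (adjusted p = 0.0734), with the 1 CPM filter (0.0595), limma-voom (0.0779) and group weights (0.0636). CD74, the invariant chain of MHC class II, rose 3.4-fold. CD79B had 106 counts in the CELF2 ASO libraries and 2 in the control libraries, a ratio of 52.8 with a 95% exact counting interval of 14.3 to 442. FCRLA, an Fc receptor-like gene of B cells, rose 18.3-fold.

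Markers of other cell types were few. Of 5 tested T and NK cell markers, 3 fell, CD8B 5.19-fold and ZAP70 2.16-fold among them, and the list was not shifted (median -0.76, camera adjusted p = 0.258, with 3 changed when adjusted over the list alone). ZAP70 lost its call without control_LNA_ASO replicate 2 (adjusted p = 0.107), with the GC and length correction (0.083) and with group weights (0.0522). Of 5 myeloid markers, 4 fell, with a median of -0.94 that stayed at -0.94 with S100A9 at its bound (camera adjusted p = 0.0457, or adjusted p = 0.297 with an estimated correlation, with 4 changed when adjusted over the list alone). That call was lost without CELF2_LNA_ASO replicate 1 (adjusted p = 0.127) or replicate 2 (adjusted p = 0.0884), with the 1 CPM filter (0.0745), limma-voom (0.0654), group weights (0.0741), the GC and length correction (0.0677) and its genes without offsets (0.0528). The myeloid call was also lost with the label's number as a block (camera adjusted p = 0.0608). FCGR1A fell 4.79-fold, and S100A9 had 76 counts in the control and 2 in the CELF2 ASO libraries, a ratio of 38.1 with a 95% exact counting interval of 10.2 to 321. Of 6 stromal and epithelial markers, 1 rose and 2 fell with no shift of the list (median 0.22, mean 0.15, camera adjusted p = 0.951, direction down, with 4 changed when adjusted over the list alone). KRT8 rose 2.57-fold and EPCAM fell 1.85-fold. The counting intervals cover counting error only.

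Signalling and survival lists were mixed. Of 27 NF-kB targets, 13 rose and 6 fell (median 0.18, camera adjusted p = 0.0147, or adjusted p = 0.301 with an estimated correlation, with 19 changed when adjusted over the list alone), a call lost with limma-voom (adjusted p = 0.0779) and with group weights (adjusted p = 0.0636). The chemokine gene CCL3 rose 7.41-fold and CFLAR 2.67-fold. Of 24 p53 targets, 12 rose and 3 fell (median 0.45, camera adjusted p = 0.00497, or adjusted p = 0.248 with an estimated correlation, with 17 changed when adjusted over the list alone). CDKN1A, a cyclin-dependent kinase inhibitor, rose 2.95-fold and the death receptor gene TNFRSF10B rose 4.08-fold. Of 27 apoptosis regulators, 11 rose and 6 fell (median 0.09, camera adjusted p = 0.0466, or adjusted p = 0.472 with an estimated correlation, with 19 changed when adjusted over the list alone), a call lost when any 1 of the 4 libraries was left out (adjusted p = 0.128 and 0.0637 without control_LNA_ASO replicates 1 and 2, and 0.141 and 0.147 without CELF2_LNA_ASO replicates 1 and 2). It was also lost with the summed control (0.0702), RLE scaling (0.0503), the 1 CPM filter (0.0502), limma-voom (0.37) and group weights (0.276). The anti-apoptotic gene BCL2 rose 3.48-fold and the pro-apoptotic gene HRK rose 13.9-fold. Of 17 immediate early genes, 7 rose and 8 fell, with a median of -0.33 against a mean of 0.03 (camera adjusted p = 0.925, direction up, with 16 changed when adjusted over the list alone), with BTG2 2.4-fold higher and DUSP2 2.62-fold lower. Of 33 myeloma oncogenes and drug targets, 10 rose and 12 fell (median -0.03, camera adjusted p = 0.951, direction up, with 22 changed when adjusted over the list alone), and CCND1 fell 2.23-fold.

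Type I interferon response genes differed between the CELF2 ASO libraries. Relative to the control mean, their median log2 level was 0.37 in CELF2_LNA_ASO replicate 1 and 1.54 in CELF2_LNA_ASO replicate 2. Of 41 tested members, 3 rose and 1 fell, with a median of 1.08 (camera adjusted p = 0.00406, or adjusted p = 0.853 with an estimated correlation, with 2 changed when adjusted over the list alone). The estimated correlation was 0.98 against the preset 0.01, and fry did not call the list (fry adjusted p = 0.356). STAT2, a transcription factor of this response, rose 4.94-fold and IRF9 1.69-fold, but STAT2 lost its call without control_LNA_ASO replicate 1 (adjusted p = 0.0725) or replicate 2 (adjusted p = 0.0922) and with these summed (0.0939), and IRF9 without control_LNA_ASO replicate 1 (adjusted p = 0.0609). IFIT2 had 23.04 and 83.24 CPM in the CELF2 ASO libraries against 6.18 and 6.86 CPM in the control and did not pass (edgeR adjusted p = 0.0604). It passed with library totals alone (adjusted p = 0.0211), the 1 CPM filter (0.0207), DESeq2 (0.00162), limma-voom (0.016), the label's number as a block (0.0143), group weights (0.00143), and on the genes with GC and length values (0.0444). It also passed without CELF2_LNA_ASO replicate 1 (adjusted p = 1.81e-110) or replicate 2 (adjusted p = 8.46e-42), fits that leave out the difference between these libraries and use the spread of the control pair alone. The number of members that changed was 21 with limma-voom and ran from 1 to 34 over the alternatives, the lowest without a control library and the highest without CELF2_LNA_ASO replicate 1.

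**Figure D3:**
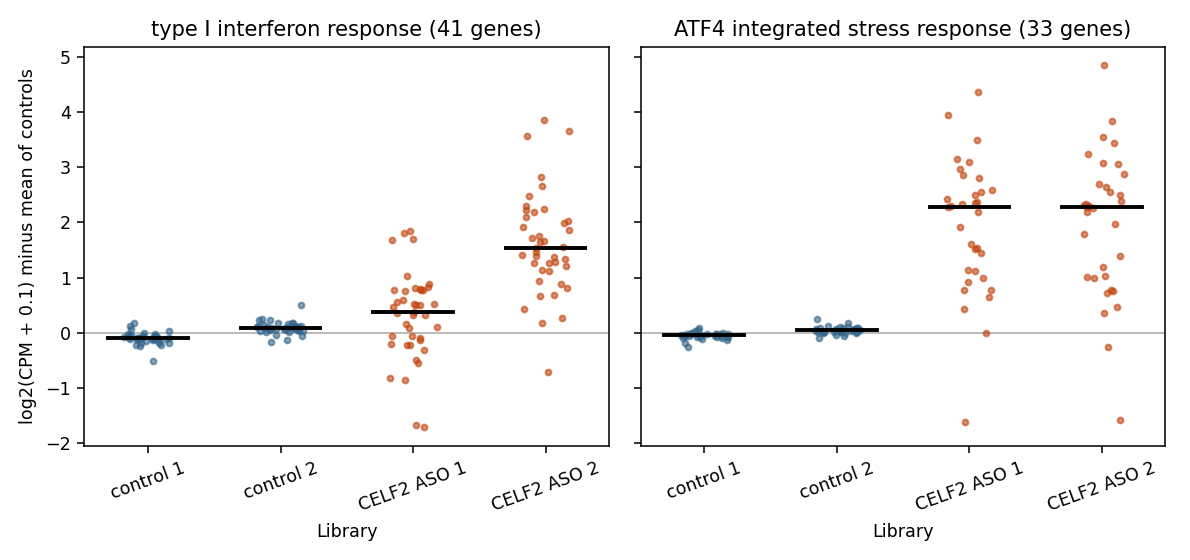
Log2 of CPM plus 0.1, minus the mean of the control libraries (y axis), for each tested gene of the type I interferon (41) and ATF4 (33) lists in each library (x axis), with a bar at each median. The interferon median is 0.37 in CELF2 ASO library 1 and 1.54 in library 2, while the ATF4 medians are 2.27 and 2.29.

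Changes were ranked among genes past the threshold with a mean log2 CPM of at least 1, a symbol and groups that did not overlap. List members below that level, such as CD22 and S100A9, were not ranked. The 8 largest rises and 8 largest falls in this ranking fell outside the lists. LINC01512 had 320 counts in the CELF2 ASO libraries and 1 in the control libraries, a ratio of 319 with a 95% exact counting interval of 56.8 to 12600. The next largest rises in this ranking were GPR84 (76.6-fold), the sodium channel gene SCN4A (58.8-fold), GNAO1 (54.7-fold), the trypsinogen gene PRSS1 (45.4-fold), KLHDC7B (41.6-fold) and PRDM16 (29.1-fold). The largest falls in this ranking were KRT6C (66-fold), OLFML2B (54.9-fold), PCP4 (26.9-fold), KRT81 (24.4-fold), KRT86 (22.5-fold), IGFBP3 (22.3-fold), CXCR3 (20.3-fold) and FRMD1 (19.4-fold). GPR84, KLHDC7B, PRDM16 and IGFBP3 lost their calls without control_LNA_ASO replicate 1 (adjusted p = 0.264, 0.0892, 0.133 and 0.22), without control_LNA_ASO replicate 2 (adjusted p = 0.288, 0.126, 0.199 and 0.229) and with these libraries summed (0.256, 0.102, 0.159 and 0.218). With no filter GPR84, PRDM16 and IGFBP3 lost theirs (0.104, 0.0549 and 0.0623).

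Across the lists, camera called 8 shifted up and 11 down. With an estimated inter-gene correlation it called 0, with 5 lists at an unadjusted p under 0.05, and fry called 17. The called lists that fry left out were the type I interferon and cytosolic ribosomal lists (fry adjusted p = 0.356 and 0.197). Those lists had estimated correlations of 0.98 and 0.75. The p53, earlier B cell and myeloid lists had estimates of -0.04, -0.011 and -0.16, below the preset 0.01. Their unadjusted camera p still rose, from 0.00268, 0.0191 and 0.0317 to 0.0796, 0.129 and 0.16. A higher correlation is therefore not why these lists lost their calls. The other called lists had estimates above 0.01. With an estimated correlation camera also takes its degrees of freedom from the libraries and not from the genes. With 2 libraries per group few remain, which raises p, and even the ATF4 list had an unadjusted camera p of 0.0207. The loss of calls therefore does not by itself show that inter-gene correlation accounts for the shifts.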

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

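The GC and length correction, the weights per group and the summed control were chosen after the data were seen. Across all alternatives the changed genes numbered 7719 to 12313, the lower genes 4155 to 6274 and the genes changed at least 2-fold 3892 to 5553, each within 1.5 times its main value, and CELF2 stayed lower with a log2 fold change between -1.45 and -1.16. Leaving out each library gave 3564 to 6214 higher genes, the lowest without control_LNA_ASO replicate 1, where a lone control library is assumed to vary like the CELF2 ASO pair. A lone CELF2 ASO library is assumed to vary like the control pair, which differed less, so calls gained in those fits are no evidence of stability. Of the changed genes that were also tested there, 68.6% kept their call in that fit and 79.8% with DESeq2, which called 8725. Gene lists shifted went from 19 to 0 with an estimated correlation, also where it was below 0.01. That version has few degrees of freedom with 2 libraries per group, so the 0 says little about the lists.

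No label says that the number pairs the libraries, and it was not taken to do so. The number 2 minus number 1 differences of the groups correlated at 0.068 across 12788 genes, which are not independent replicates, although interferon genes were higher in number 2 and mitochondrial ribosomal RNA in number 1 of both groups. With the replicate block 10790 genes changed, 5411 higher and 5379 lower, 5071 at least 2-fold, 18 lists were shifted and CELF2 had a log2 fold change of -1.28. With the block the myeloid list had an adjusted p of 0.0608 and IFIT2 of 0.0143, and no other call on a list or named gene changed. Scaling by library totals alone moved the median of all genes from 0.043 to 0.159, with 58.3% of the calls higher, so directions of genes near 0 are relative to that shift.

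Among the named genes and the lists, those that reversed had not passed. Of 10119 changed genes with GC and length values, 80 had the opposite sign under that correction, and 0 of the changed genes tested there did under each other alternative. The cause of these reversals was not tested. XBP1 was -0.002 with RLE scaling and DESeq2, -0.034 with no filter, -0.02 with the summed control, -0.043 with the GC and length correction and -0.054 to 0.084 without 1 library. ISG15 was -0.009 with limma-voom, -0.003 with the block, -0.012 with group weights and -0.851 to 0.816 without 1 library. MX1 was 0.016 with library totals and -0.886 to 0.428 without 1 library, and HSPD1 was -0.013 with the GC and length correction. Over all named genes and alternatives, a call was lost 37 times and gained 13 times without a change of sign, and at the preset correlation a list lost its call 26 times. Medians of lists reversed likewise. The CELF and MBNL family was -0.281 with no filter and -0.235 to 0.214 without 1 library. Stromal and epithelial markers were -0.405 with no filter, -0.116 with the 1 CPM filter and -0.273 to 0.268 without 1 library. T and NK cell markers were 0.159 with no filter. Mitochondrially encoded mRNAs were -0.01 with no filter, -0.034 with the GC and length correction and -0.012 to 0.058 without 1 library. Myeloma oncogenes and drug targets were 0.084 with library totals and -0.081 to 0.041 without 1 library, plasma cell identity genes -0.267 to 0.041 without 1 library, and immediate early genes 0.166 with the GC and length correction. In simulated counts of this depth, with 200 of 18810 genes changed and a spread shared by both groups, 49.3% of 1.5-fold changes were recovered. In the data 55.6% of the tested genes were called and the groups differed in spread, so this share does not carry over directly.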

Other observations

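The tests of one common factor and of both histone explanations, and the immunoglobulin groups, were chosen after the related results were seen. All 12 tested immunoglobulin lambda genes rose with the CELF2 ASO, with a median log2 fold change of 2.39, and they took 1.96% and 1.9% of counts against 0.278% and 0.356% in the control libraries. IGLC2 was 5.79-fold and IGLV2-14 5.49-fold higher, calls lost without CELF2_LNA_ASO replicate 1 (edgeR adjusted p = 0.059 and 0.0705) or replicate 2 (0.0639 and 0.0767). The group was formed after such genes were seen to rise and near-identical segments share reads, so no p-value is given for it. Among 11 heavy and kappa chain genes, 2 rose and 5 fell. Those that fell reached at most 1.83 CPM in any library (IGHG1), so their falls lie near the floor. Those that rose, IGKC and IGKJ1, had log2 fold changes of 0.22 and 0.45. HMOX1, which encodes heme oxygenase 1, fell 16.7-fold from 674 ± 3.34 to 40.3 ± 8.41 CPM (SD, n = 2; edgeR adjusted p = 5.48e-06).

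Of the tested genes, 55.6% were called changed, and fold changes followed GC content (Spearman rho -0.27 across 10695 genes, with medians from 0.14 in the lowest GC decile to -0.62 in the highest). Offsets that remove each library's trend with GC and length left 10191 of 17699 genes called, against 10198 without offsets, with 89.8% against 98.3% of the original calls kept and 80 of their signs turned, which argues against such a trend as the whole cause. With libraries scaled by totals alone, which leaves in place a shift by one factor from a few abundant RNAs, 34% of the 5126 calls of at least 2-fold lay in the smaller direction, which argues against that shift as the whole cause. With the control libraries summed to 1, so that the spread came from the CELF2 ASO pair alone, 8746 genes were called and 77.6% of the calls were kept, which argues against control libraries that understate the spread as the whole cause. An effect of CELF2 loss, an effect of this oligonucleotide on other RNAs and a difference between transfected cultures stay open, since the design has 1 contrast and no label separates them.

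Replication-dependent histone genes were lower. A lower yield of RNA without a poly(A) tail may produce this, but 49 tested small RNA genes had a median log2 fold change of 0.03 (SD 0.69). Of these, 27 were of the type that holds 7SL and 7SK copies, which share reads. The other 22, small nuclear, nucleolar and Cajal body RNA genes, had a median of -0.22 (SD 0.74), 1.39 above the histone median. This argues against a loss shared by these small RNAs as the whole cause. The labels leave the library method unsettled, although the abundance of RN7SL1 and SNORD3A in all 4 libraries argues against poly(A) selection. Small RNAs may not stand for histone mRNAs, and a loss of histone mRNAs alone was not tested. Fewer cells replicating DNA is a candidate explanation, and the G1/S list had a median of -0.6. Polyadenylated replacement histones lay 1.57 above the replication-dependent ones in median log2 fold change. A lower yield of RNA without a poly(A) tail would give that gap too, so the gap does not separate these explanations. Cell cycle phase was not measured, so this remains a hypothesis.

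Interferon genes were higher in CELF2_LNA_ASO replicate 2 than in replicate 1, in all 41 tested members, by a median log2 difference of 1.27. With GC and length offsets the difference was 1.29, which argues against that trend. Its percentile was 100 among 10000 random lists matched on expression, whose highest median was 0.16, which argues against scaling or depth. The control libraries also differed, by 0.18 in the same direction, with 37 members higher in replicate 2. The replicate number may mark a different oligonucleotide or culture, which no label settles, so no biological explanation was tested.

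A hypothesis was that an ATF4 program would raise the cytosolic aminoacyl-tRNA synthetases reported as its targets more than the others. The 9 reported targets that were not already in the ATF4 list had a mean log2 fold change of 0.81 ± 0.43 and the other 8 a mean of -0.69 ± 0.64 (SD over genes). The difference of 1.5 had a one-sided exact permutation p of 8.23e-05 over 24310 splits of the genes, which are not independent replicates. This is consistent with an ATF4 program, and it does not say what started it.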
